A study of Mus musculus with 2 samples.

How the data were processed

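The series holds long-read RNA sequencing of total RNA from hippocampus of female B6CASTF1/J mice aged 14 days, in 1 group of 2 libraries. The source label names the tissue as layer of hippocampus. Per the labels, each library is a pool of 3 animals, started from 2 µg of RNA, and held ERCC and SIRV spike-in RNAs. Replicate 1 holds 1168366 reads and replicate 2 holds 888704.

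The deposited values are raw read counts per transcript model, 1 table per library, not scaled, per the file headers and the values. The authors aligned reads to mm10 and assigned them to GENCODE M21 transcripts plus models made from each library's own reads, per the file headers, and TALON is named as the source of the added models in the deposited annotation. The aligner, the versions and the read filters are not given in the sources used here. Model lengths in nt, exon numbers and coordinates were taken as deposited. Models with 1 read were listed, so no filter on the added models was evident. The annotation holds sequences of ERCC spike-ins and not of SIRV.

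From the deposited counts, CPM were computed over all reads of a table, spike-ins included. Unannotated models were matched between libraries by chromosome, strand and intron chain. Classes follow the deposited names: annotated, incomplete splice match, new combination of annotated sites, unannotated site, genomic, antisense and intergenic. A gene's reads are those of all models carrying its identifier.

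Genes with at least 10 reads over both libraries were tested with a two-sided exact binomial test of the read split against the split of library totals, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 ratios of CPM used an added 1 CPM. Leading transcript use was tested with Fisher's exact test in genes with at least 20 reads in each library, and exon inclusion with the same test. A cassette event is an internal exon whose inclusion and skipping between the same flanking sites are both annotated, with at least 20 reads over both forms in each library. Microexons are those of at most 27 nt, compared with longer ones by 100000 resamples of a two-sided permutation test (smallest possible p 1e-05). Exons, not animals, are the unit there and in the frame test. The biological coefficient of variation is the square root of the common dispersion of edgeR 4.0.16 with TMM factors. DESeq2 1.42.0 gave median-ratio size factors as an alternative. TMM-scaled totals are TMM factors times the reads of annotated genes with at least 10 reads. Antisense, intergenic and spike-in reads are outside those totals. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

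The tests, lists, thresholds, alternatives and the rule for named genes were fixed before the data were examined, apart from 5 alternatives added later. These were merged overlapping genes, removal of the trend with transcript length, exons of 15 to 27 nt, TMM-scaled list levels and 1-exon models pooled across classes. The rule named, for each list, the 4 members with the highest mean CPM and members with 0 reads in both libraries. It also named the 10 genes with the highest mean CPM, isoform list genes with their leading transcripts and exons, the 5 unannotated spliced transcripts with the most reads in both libraries, the 5 genes with the largest fold in each direction, the 5 with the largest difference in leading share, the 10 microexons with the most reads and the 3 unannotated loci with the most reads. Ddx5, Rtn1, Gpm6b, Usp15 and Enpp2 were named after their values were seen, as were the genes of the closing section outside that rule.

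The gene lists were pan-neuronal, excitatory neuron, dentate granule cell, CA1, CA2/CA3, inhibitory interneuron, astrocyte, myelinating oligodendrocyte, oligodendrocyte precursor, microglia, endothelial and mural, choroid plexus and ependyma, blood, meningeal fibroblast, immature neuron, proliferation, thalamus, striatum, neocortex layer, AMPA, NMDA, kainate, metabotropic and GABA-A receptor, postsynaptic density, synaptic vesicle release, splicing regulator, immediate early, long non-coding RNA, Y-linked and isoform genes. They were written from general knowledge of the field. Tissue RNA does not show which cell type a read came from, so a list sum is not a measure of that cell type alone.

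Other alternatives were other scalings and read minimums, annotated transcripts only, other limits for the second transcript, exon length and inclusion, and each library left out in turn. The tests were tested on simulated data. With 11679 genes, 67% of genes changed 2-fold and 95% of those changed 4-fold were recovered and 4 unchanged genes were called. Of genes shifted by 30 points in leading share 87.5% were recovered, with 6 unchanged among 6607 called. A simulated coefficient of variation of 0.2 came back as 0.199. Antisense and intergenic loci were left out of the gene comparisons and are described in the closing section. Some genes that the rule would name are not reported here. The parental alleles of the hybrid cannot be told apart in these tables.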

Results

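Long-read RNA sequencing reads a cDNA copy of a transcript as 1 read, so each read carries the order of the exons it came from. The series applied it to hippocampus (labelled layer of hippocampus tissue) of female B6CASTF1/J mice, the F1 hybrid of C57BL/6J and CAST/EiJ, at 14 days of age. It holds 1 group with 2 biological replicates, and each replicate is 1 library made from a pool of 3 animals. The sample characteristics number different animals for each library, 6 in all, while a description line of both libraries repeats the animal numbers of replicate 1. There was no second condition. The design therefore implies a description of which genes, cell-type markers, transcript forms and exons were read in this tissue, and a comparison of the 2 libraries with each other. Replicate 1 held 1168366 reads over 143443 transcript models and replicate 2 held 888704 reads over 126438 models, and 59.9% and 62.3% of the models rested on 1 read. One read was worth 0.856 CPM (reads of a gene per 1e6 reads of its library) in replicate 1 and 1.13 CPM in replicate 2. All tests between the libraries below treat reads as the unit, so they compare these libraries and not conditions. Binomial intervals and limits are exact Clopper-Pearson intervals at 95% or the limit that a count of 0 allows (3 reads), and they cover counting error only.

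The hippocampus libraries were led by genes of neurons, astrocytes and myelin. Apoe, the main lipid carrier released by astrocytes, had the highest mean level at 7497 ± 259 CPM (SD, n = 2; ENSMUSG00000002985.16, mm10 chromosome 7, 19696109 to 19698267). The tubulin genes Tuba1a and Tubb2a followed with 6470.4 ± 521 and 5350.5 ± 169 CPM, and the calmodulin gene Calm2 had 3127 ± 594 CPM. Tubulin and calmodulin genes have close copies, and how reads were shared among copies is not given in the sources used here. Also among the 10 highest were Cpe, a peptide-processing carboxypeptidase (4993 ± 1145 CPM), Ubb, a polyubiquitin gene (4228 ± 589 CPM), Mbp, the myelin basic protein gene (3834 ± 774 CPM), Cst3 (2809 ± 484 CPM) and Fth1 (2537 ± 391 CPM). The 10 highest genes together took 4.63% of the reads. In all, 15151 annotated genes had at least 1 read in each library, 17540 in replicate 1 and 16653 in replicate 2, of 55536 in the annotation. Protein-coding genes made up 13358 of the 15151 and held 87.1% ± 2.45 of the reads (SD, n = 2), while long intergenic RNA genes held 0.384% ± 0.0571. Mitochondrial genes held 772 and 520 reads, or 0.0661% and 0.0585%.

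Neuronal markers were abundant, and each listed marker of the granule cells and pyramidal fields of the hippocampus was read in at least 1 library. The least read of them, in the CA2/CA3 list, had 0 reads in replicate 1 and 1 in replicate 2. The 10 pan-neuronal genes summed to 5833 ± 528 CPM (SD, n = 2), with the neurofilament gene Nefl at 1731 ± 263 CPM and the vesicle fusion gene Snap25 at 1290.4 ± 109 CPM. The excitatory markers summed to 3706 ± 38.9 CPM (1276 with annotated transcripts only), where Nrgn, a postsynaptic calmodulin-binding protein, reached 1999 ± 207 CPM and the vesicular glutamate transporter gene Slc17a7 1242 ± 157 CPM, while Camk2a stood at 129 ± 11.7 CPM. Dentate granule cell markers summed to 451 ± 134 CPM (Calb1 219.5 ± 38.1, C1ql2 112 ± 42.8, Prox1 22.6 ± 22.2), CA1 markers to 474 ± 51.97 CPM (Wfs1 133 ± 35.9, Mpped1 123 ± 19.6) and CA2/CA3 markers to 688 ± 95.2 CPM (Pcp4 272 ± 62.6, Bok 208 ± 24.7). Interneuron markers summed to 951 ± 179 CPM. Cck made up most of that sum at 516 ± 200.5 CPM, ahead of the GABA-synthesising enzyme gene Gad1 at 204 ± 45.4, Npy at 60.4 ± 18.6 and Sst at 42.1 ± 27.7 CPM. Which cells the Cck reads came from cannot be told here, so the sum is not a level of interneurons alone. Markers of neighbouring regions were low: 92.6 ± 2.12 CPM for thalamus (Prkcd 47.1 ± 9.75), 85.7 ± 1.35 CPM for neocortex layers (Fezf2 31.3 ± 1.89) and 61.4 ± 4.02 CPM for striatum (Ppp1r1b 47.5 ± 1.87). Gbx2 of the thalamus list had no read in either library, which allows up to 2.57 and 3.38 CPM. With annotated transcripts only the sums fell to 304 CPM for CA1, 569 for interneurons and 58.4 for thalamus.

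Astrocyte and myelin markers had higher sums than those of other glia. The astrocyte list summed to 4622 ± 1415 CPM (SD, n = 2), with the glycolytic enzyme gene Aldoc at 1573 ± 481, the gap junction gene Gja1 at 821 ± 280.3 and the glutamate transporter gene Slc1a3 at 734 ± 283 CPM. The myelinating oligodendrocyte list summed to 5739 ± 1167 CPM, most of it from Mbp (3834 ± 774 CPM), followed by Cnp (901 ± 208 CPM). Oligodendrocyte precursor markers summed to 599 ± 94.6 CPM (373 with annotated transcripts only; Olig1 204 ± 48.8), microglial markers to 698 ± 121 CPM (C1qc 83.7 ± 0.969) and endothelial and mural markers to 557 ± 52.1 CPM (Cldn5 296 ± 9.47, Rgs5 119 ± 21.5). Markers of immature neurons summed to 397 ± 31.7 CPM (Calb2 141 ± 3.80, Tubb2b 127 ± 16.1), and the 6 proliferation genes to 76.9 ± 5.84 CPM, mostly Pcna at 52.6 ± 11.5. Globin and other blood genes summed to 469 ± 157 CPM (Hba-a1 235 ± 78.7, Hbb-bs 135 ± 42.0). The globin genes are near-identical pairs, so the split between copies is uncertain, and Slc4a1 had no read. Meningeal fibroblast genes summed to 135 ± 25.6 CPM (Col1a1 48.9 ± 7.10, Dcn 45.2 ± 9.87). Of the 29 gene lists other than the Y-linked and isoform lists, 23 summed to at least 100 CPM in both libraries. The 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had no read in either library of these female mice.

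**Figure D1:**
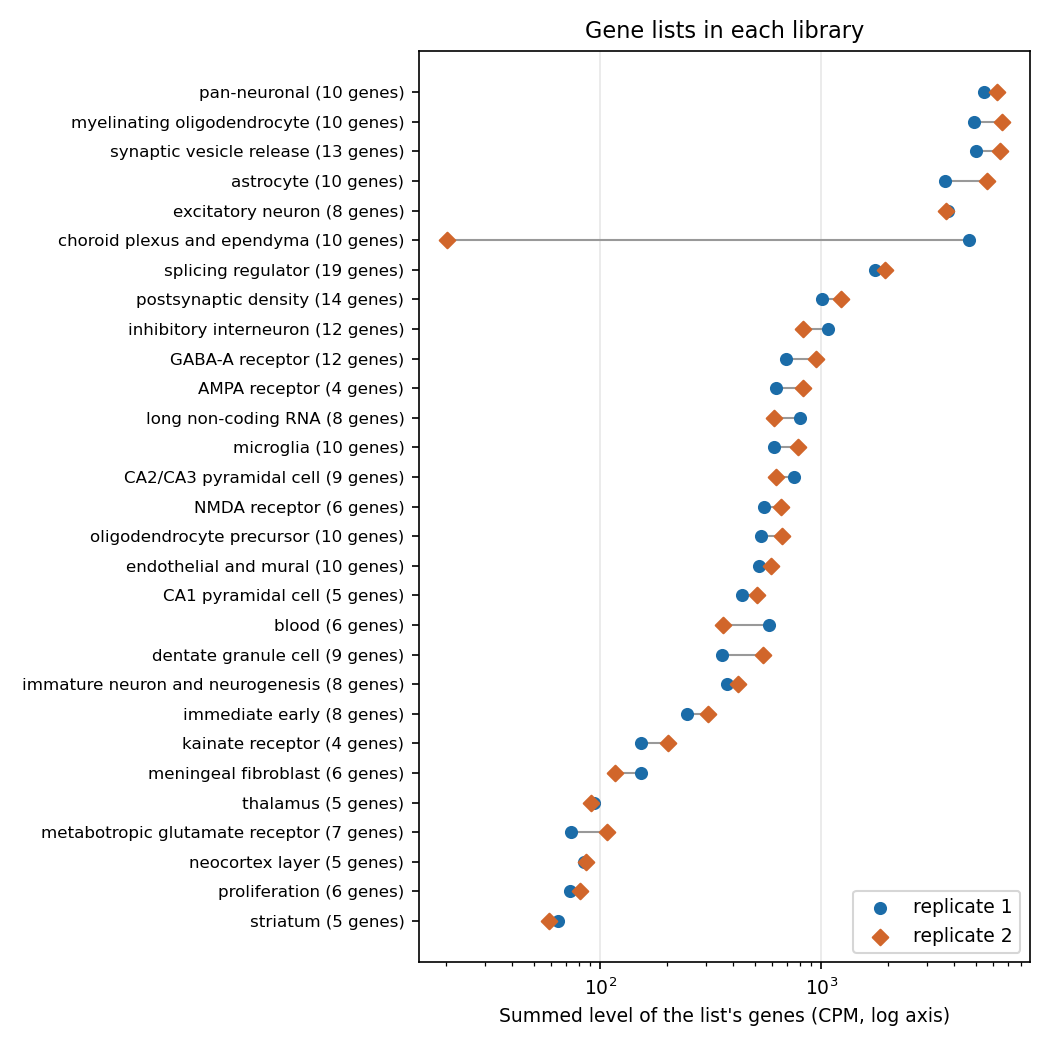
Summed level of the genes of each list (CPM, log axis) in replicate 1 (circles) and replicate 2 (diamonds), with a line joining the 2 libraries. The choroid plexus and ependyma list stands at 4678 CPM in replicate 1 and 20.3 CPM in replicate 2, and the other lists lie within a narrower span.

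Transmitter receptor genes differed widely in level within each family. Gria2 (362 ± 71.7 CPM) and Gria1 (285 ± 57.5 CPM) led the AMPA receptor genes, above Gria3 (46.1 ± 9.56) and Gria4 (30.01 ± 3.71; SD, n = 2), of a family sum of 723 ± 142 CPM. The NMDA receptor genes summed to 603 ± 73.9 CPM, and the obligatory subunit gene Grin1 had 419 ± 81.2 CPM, against 66.0 ± 26.5 for Grin2b and 59.2 ± 24.4 for Grin2c. Gabra5, a GABA-A subunit gene enriched in hippocampus, led the 823 ± 180.3 CPM of its family at 332 ± 78.2 CPM, and Gabrb1 had 72.0 ± 9.53. Grik5 made up 155 ± 30.5 of the 178 ± 35.7 CPM of the kainate receptor genes, and the 7 metabotropic receptor genes summed to 90.3 ± 23.5 CPM (Grm3 24.7 ± 9.57, Grm5 24.2 ± 0.842). Vesicle release genes summed to 5729 ± 999.01 CPM (Syp 1345 ± 105, Vamp2 1117 ± 193, Nsf 801 ± 166) and postsynaptic density genes to 1118 ± 162 CPM (Dlgap1 173 ± 42.9, Dlgap3 166 ± 30.6). No list sum here or above holds reads antisense to its genes, which exceeded the sense reads at some of them (closing section). The 19 splicing regulator genes summed to 1846 ± 142 CPM, with Celf4 at 485 ± 79.5, Khdrbs3 at 364 ± 53.7 and Qk at 202 ± 54.7 CPM. The 8 long non-coding RNAs summed to 705 ± 130.4 CPM, with the imprinted Meg3 at 354 ± 52.2 CPM and Malat1 at 100.7 ± 29.4 CPM. Immediate early genes summed to 277 ± 42.9 CPM (Junb 128 ± 18.4, Arc 60.8 ± 0.00424), and Fosb had no read. With annotated transcripts only the sums were much lower: 443 CPM for AMPA, 262 for NMDA, 56.6 for kainate, 20.8 for metabotropic and 511 for GABA-A receptor genes, 387 for postsynaptic density genes, 787 for splicing regulators and 141 for long non-coding RNAs.

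The 2 libraries differed most in Ttr, the transthyretin gene that choroid plexus epithelium expresses at very high level. Ttr (ENSMUSG00000061808.4, chromosome 18, 20665280 to 20674321) had 5325 reads in replicate 1 and 5 in replicate 2, or 4558 and 5.63 CPM, a log2 ratio of replicate 2 over replicate 1 of -9.43. Of the 6 genes of the choroid plexus and ependyma list with at least 10 reads, 5 were higher in replicate 1, also when adjusted over the list alone (two-sided exact binomial test of the read split, Benjamini-Hochberg adjustment). Kcnj13 had 49 reads and Clic6 22 reads in replicate 1 and none in replicate 2. Rarres2 did not pass, with 13.7 and 4.50 CPM. Astrocyte genes went the other way: 7 of 10 were higher in replicate 2, 9 when adjusted over the list alone, with Aldoc at 1233 and 1913 CPM, Gja1 at 623 and 1019 CPM and Slc1a3 at 533 and 934 CPM. That count was 6 with TMM-scaled totals and 5 once a trend with transcript length was removed. Of the 9 myelinating oligodendrocyte genes tested 3 were higher in replicate 2 (Mbp and Cnp among them), of the 13 vesicle release genes 6, and of the 10 pan-neuronal genes 4, and the counts adjusted over the list alone were 3, 7 and 6. With the length trend removed they were 2, 2 and 1, and with TMM-scaled totals 3, 4 and 2, where 2 further pan-neuronal genes became higher in replicate 1. All 4 globin genes were higher in replicate 1, and none of them with the length trend removed. Cck (658 and 375 CPM) and Sst (61.6 and 22.5 CPM) were higher in replicate 1 and Gad1 (172 and 236 CPM) in replicate 2, but Gad1 did not pass with TMM-scaled totals and none of the 3 passed with the trend removed.

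The other lists held few differing genes by the same exact binomial test. Higher in replicate 2 were 2 dentate granule cell genes (C1ql2 and Prox1; 3 adjusted over the list alone, 2 with the trend removed), 1 CA1 gene (Wfs1), 1 oligodendrocyte precursor gene (Olig1), 2 microglial genes (P2ry12 among them; 4 over the list alone, 1 with TMM-scaled totals and 1 with the trend removed) and 1 immature neuron gene (Neurod1). So were 2 AMPA receptor genes (Gria1 and Gria2), 3 GABA-A receptor genes (Gabra5 among them) and 2 postsynaptic density genes (Dlgap1 and Homer3). With TMM-scaled totals none of the AMPA, postsynaptic density, CA1 and oligodendrocyte precursor genes passed, and with the trend removed none of these and none of the other receptor genes did. Pcp4 of the CA2/CA3 list was higher in replicate 1, but with the trend removed no gene of that list or of the immature neuron list passed. Nrgn was higher in replicate 1 and Slc17a7 in replicate 2, Grin2b in replicate 1 and Grin1 and Grin2c in replicate 2, and Khdrbs3 in replicate 1 and Celf4 and Qk in replicate 2. With TMM-scaled totals the excitatory list had 2 genes higher in replicate 1 and none higher in replicate 2, and Grin1 and Grin2c did not pass. With the trend removed no excitatory gene or splicing regulator was higher in replicate 2, and 1 of each was higher in replicate 1. Of the long non-coding RNAs 2 were higher in replicate 1, Malat1 among them, and 4 over the list alone. With TMM-scaled totals 4 were, and with the trend removed 3. No gene passed in the endothelial and mural, meningeal, proliferation, thalamus, striatum, neocortex, metabotropic receptor and immediate early lists, and none of the kainate receptor genes, where 1 passed over the list alone. In the isoform list 1 gene was higher in replicate 1 and 19 in replicate 2 (2 and 22 over the list alone; 2 and 11 with TMM-scaled totals; 0 and 4 with the trend removed). The vesicle release count includes Cplx2, whose replicate 1 reads mostly carried another gene's name.

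**Figure D2:**
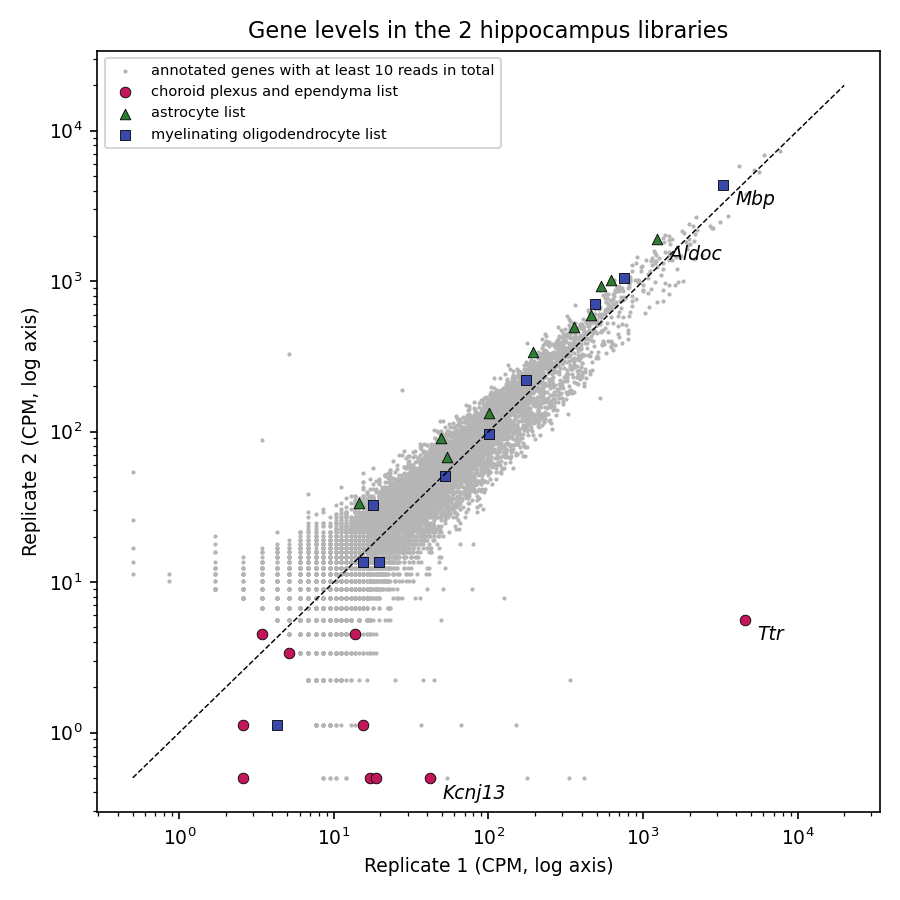
Level of each annotated gene with at least 10 reads in total in replicate 1 (x axis, CPM, log) and replicate 2 (y axis, CPM, log), with the members of 3 gene lists as larger symbols and the line of equal level dashed. Genes with no read in a library are drawn at the lowest value of that axis. Ttr lies at 4558 and 5.63 CPM, and Kcnj13 at 41.9 CPM in replicate 1 with no read in replicate 2.

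In the whole set, 1266 of 11681 genes with at least 10 reads differed between the libraries (10.8%; two-sided exact binomial test, adjusted p at most 0.05), 679 higher in replicate 2 and 587 higher in replicate 1. Using TMM-scaled totals in place of library totals moved all genes by -0.13 on the log2 scale. That shift combines the TMM factors with the change from all reads to reads of annotated genes. The split became 346 higher in replicate 2 and 792 higher in replicate 1. Across genes, which are not independent replicates, log2 CPM correlated with Pearson's r = 0.926 and Spearman's rho = 0.930. The median absolute log2 difference of the 1713 genes with at least 100 reads in each library was 0.31. The biological coefficient of variation was 0.211, and the mean chi-square per gene against sampling noise was 4.29. Short transcripts were higher in replicate 1 and long ones in replicate 2. Over 6302 genes with at least 50 reads in total the log2 ratio of replicate 2 over replicate 1 correlated with transcript length (Spearman's rho = 0.510 across genes). Its median was -0.68 for the 478 genes with transcripts of 500 to 1000 nt and 0.31 for the 1305 genes above 4000 nt. The ERCC spike-in RNAs, added in known amounts, had medians of -0.82 for 7 species of 500 to 1000 nt and -0.43 for 10 species of 1000 to 2000 nt. They took 1.72% of the reads of replicate 1 and 1.15% of replicate 2. With the length trend removed 393 genes differed, 220 of them higher in replicate 1, and 290 of the 393 were among the 1266.

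**Figure D3:**
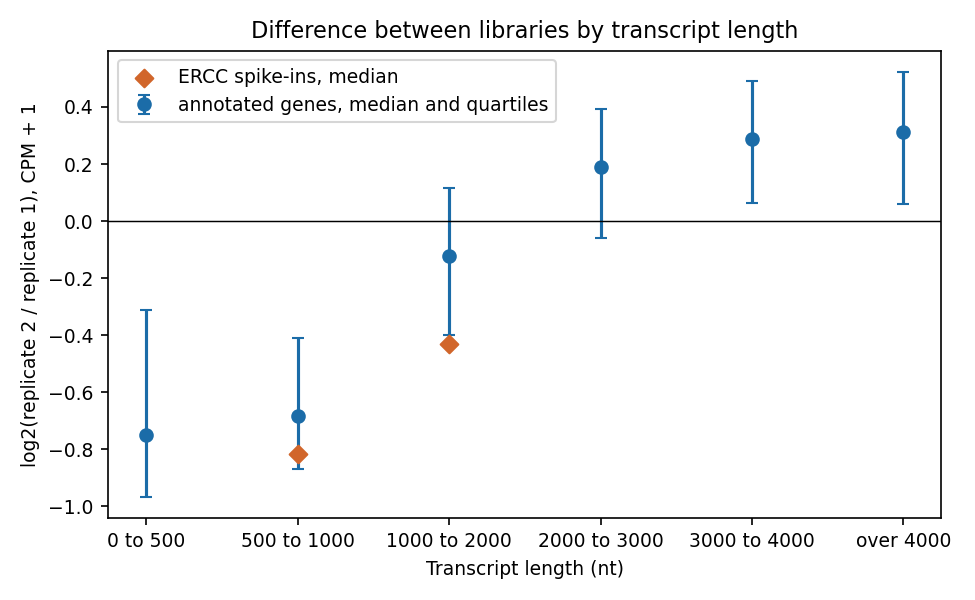
Log2 ratio of replicate 2 over replicate 1 (CPM with 1 added) by transcript length in nt, as the median and quartiles of annotated genes (circles) and the median of the ERCC spike-ins (diamonds). The gene median goes from -0.68 at 500 to 1000 nt to 0.31 above 4000 nt.

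Besides Ttr, the genes with the largest folds between the libraries were mostly loci where the same-strand reads carried another name in the other library. Klhl10 had 485 reads in replicate 1 and none in replicate 2, at least 123-fold higher, but over the span of its leading 1-exon model (chromosome 11, 100455536 to 100461670) replicate 2 had 223 reads given to an intergenic locus. Gm48623 had 389 reads in replicate 1 and none in replicate 2, and the complexin gene Cplx2 6 and 292. Their 1-exon models lie on the same stretch (chromosome 13, 54379988 to 54383917), which held 391 reads in replicate 1 and 359 in replicate 2 under all names. Tcte1 (208 and 0 reads) had 126 replicate 2 reads named as an antisense locus. In the other direction, Vil1 (0 and 23 reads) and 4930562C15Rik (0 and 15) had 34 and 12 replicate 1 reads under other names over the leading model. Gm49450 (396 and 2 reads) lies within Tuba1a, and Pcdhga2 (0 and 48 reads) shares its stretch with other protocadherin genes, whose reads make up most of these loci, so a change of name could not be read from the totals. Ttr had 5325 and 5 reads over its interval under any name.

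Most reads were assigned to an annotated transcript, which does not show that a read spanned that transcript from end to end. The share of reads on annotated transcripts, spike-ins included, was 65.3% ± 0.959 (SD, n = 2), at 64.6% (95% interval 64.6 to 64.7) in replicate 1 and 66.0% (65.9 to 66.1) in replicate 2. Leaving out spike-in reads from the remaining classes, incomplete splice matches, which hold part of an annotated exon chain, took 9.48% ± 0.0999 of reads. Spliced transcripts with a new combination of annotated splice sites took 5.59% ± 0.958, those with an unannotated site 3.54% ± 0.346, and models of annotated genes deposited as genomic 6.69% ± 0.666. For some genes the 1-exon models were genomic in 1 library and incomplete splice matches in the other, as described below. Of the 44968 unannotated spliced transcripts in replicate 1 and 43899 in replicate 2, 12215 had the same intron chain in both, and these held 60.5% and 59.1% of the unannotated spliced reads.

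Several abundant genes were read mainly as an unannotated transcript. A transcript of Nrgn with 3 exons (chromosome 9, 37544492 to 37552904) held 94.3% ± 0.230 of the gene's reads (SD, n = 2, from 2368 and 1550 reads), and 1 of its 2 introns was unannotated. Its deposited class was unannotated site in replicate 1 and new combination of annotated sites in replicate 2. For Oaz1 and Oaz2, the antizyme genes that limit polyamine synthesis, unannotated transcripts of 5 exons held 95.1% ± 0.747 and 88.4% ± 0.505 of reads. For Cpne6, a copine gene, a 17-exon transcript held 53.1% ± 0.755, and for Apbb1, which encodes an adaptor of the amyloid precursor protein, a 14-exon transcript held 57.8% ± 0.817. All introns of the latter 4 were annotated. In Oaz1 and Oaz2 the reads matched an annotated transcript once annotated gaps of 1 or 4 nt were closed, for 96.6% and 95.8% of the reads of Oaz1 and 88.99% and 88.1% of those of Oaz2, and antizyme genes are known for a programmed frameshift.

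More than 1 transcript per gene was common. Of 5490 genes with at least 20 reads in each library, 1606 or 29.3% (95% interval 28.1 to 30.5) had a second transcript with at least 10% of the gene's reads in both libraries, leaving out incomplete, genomic and antisense models. Of the 53 genes of the isoform list 50 had enough reads. An annotated transcript led in 26 of the 50, and in 17 the leading model held over 50% of reads in both libraries. The leading annotated transcript held 80.6% ± 0.677 of reads in Snap25, 73.1% ± 0.725 in the amyloid precursor gene App, 82.7% ± 3.10 in the small GTPase gene Rac1 and 70.2% ± 0.103 in Pkm (SD, n = 2). It held 57.7% ± 1.67 in Fyn and 40.7% ± 5.25 in Cdc42. In the other 24 the leading model was unannotated, as in Tpm3 (64.9% ± 1.29, 8 exons) and Bin1 (40.0% ± 0.656, 18 exons). In some of these it stood for all 1-exon models of 1 class, as in Nlgn2 (99.5% ± 0.752) and Camk2a (88.0% ± 3.07).

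The AMPA receptor genes Gria1, Gria2 and Gria3 used both members of their flip and flop exon pair, and Snap25, Pkm and Fyn favoured 1 exon of theirs. The flip exon, named by the peptide it encodes, was in 57.2% ± 3.59 of reads of Gria1 (exon pair at chromosome 11, 57309769 to 57310722; 394 reads in all) and 57.9% ± 1.41 of Gria2 (chromosome 3, 80690404 to 80691434). In Gria3 it was in 76.7% ± 5.60, from 64 reads in all. Snap25 used the downstream of its 118-nt exons, exon b of the pair known as 5a and 5b, in 86.7% ± 0.707 of 2520 reads (chromosome 2, 136770057 to 136770174). The pyruvate kinase gene Pkm used the upstream of its 167-nt exons, the M1 exon, in 79.5% ± 2.35 of reads (chromosome 9, 59675029 to 59675195). Fyn used the upstream exon, that of the brain form, in 93.6% ± 2.68, and Tpm3 the upstream of its 76-nt pair in 22.0% ± 1.04 (SD, n = 2).

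Cassette exons of neuronal and myelin genes ranged from mostly skipped to almost always included. Each share is over reads that join the same flanking splice sites, not over all reads of the gene. In Mbp the 78-nt exon was in 24.8% ± 0.450 of reads (766 and 832 inclusion reads, chromosome 18, 82561778 to 82561855). The 123-nt exon was in 27.7% ± 0.741 of reads that hold the 33-nt exon before it. A further 150 and 120 reads held the 123-nt exon without that 33-nt exon and were not counted. The 168-nt exon of App that encodes the Kunitz inhibitor domain was in 4.63% ± 1.49 of such reads (chromosome 16, 85043576 to 85043743). Reads that join it to the neighbouring 57-nt exon are left out, so its share of App reads is understated. That 57-nt exon had 33 and 39 inclusion reads, against 24 and 37 for the counted form of the 168-nt exon. In Grin1 the 63-nt N-terminal cassette was in 14.5% ± 3.46 and the 111-nt C-terminal cassette in 62.2% ± 8.94 (55.9% and 68.5% in the 2 libraries). The 87-nt N-terminal exon of the tau gene Mapt was in 11.3% ± 0.302, and the 30-nt VASE exon of Ncam1 in 45.5% ± 1.35. In the clathrin light chain gene Clta the 54-nt neuronal insert was in 90.5% ± 0.536 of reads that hold the 36-nt insert. That 36-nt insert was in 75.4% ± 1.07 of reads that hold the 54-nt one. Clta reads that lack both inserts are in neither share. The 54-nt exon of Cltb, also a clathrin light chain gene, was in 72.2% ± 4.63. Mag included its 45-nt exon in 12.5% ± 2.15, and Ptbp2 its 34-nt exon in 98.9% ± 0.0277 (SD, n = 2). The isoform list gave 78 cassette events in 30 genes, 39 of them between 5% and 95%. Some differed by more between the libraries without passing, such as the 39-nt exon of Dnm1l (47% and 64.0%), the 53-nt exon of Mag (21.4% and 40%), the 33-nt exon of Camk2g (94.4% and 79.5%) and the 36-nt exon of Homer1 (97.7% and 85.2%). Over all 4450 annotated events with at least 20 reads in each library, inclusion correlated between libraries with r = 0.993 across exons. In the 1232 events between 5% and 95% the median absolute difference was 5.37 percentage points. The 1 event of 4450 that differed (two-sided Fisher's exact test, adjusted p = 3.76e-08; 135 events at an unadjusted p under 0.05) was a 75-nt exon of Enpp2, the autotaxin gene, with 6.86% in replicate 1 and 29.0% in replicate 2. Enpp2, also expressed by choroid plexus, had 525.5 and 167.7 CPM.

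**Figure D4:**
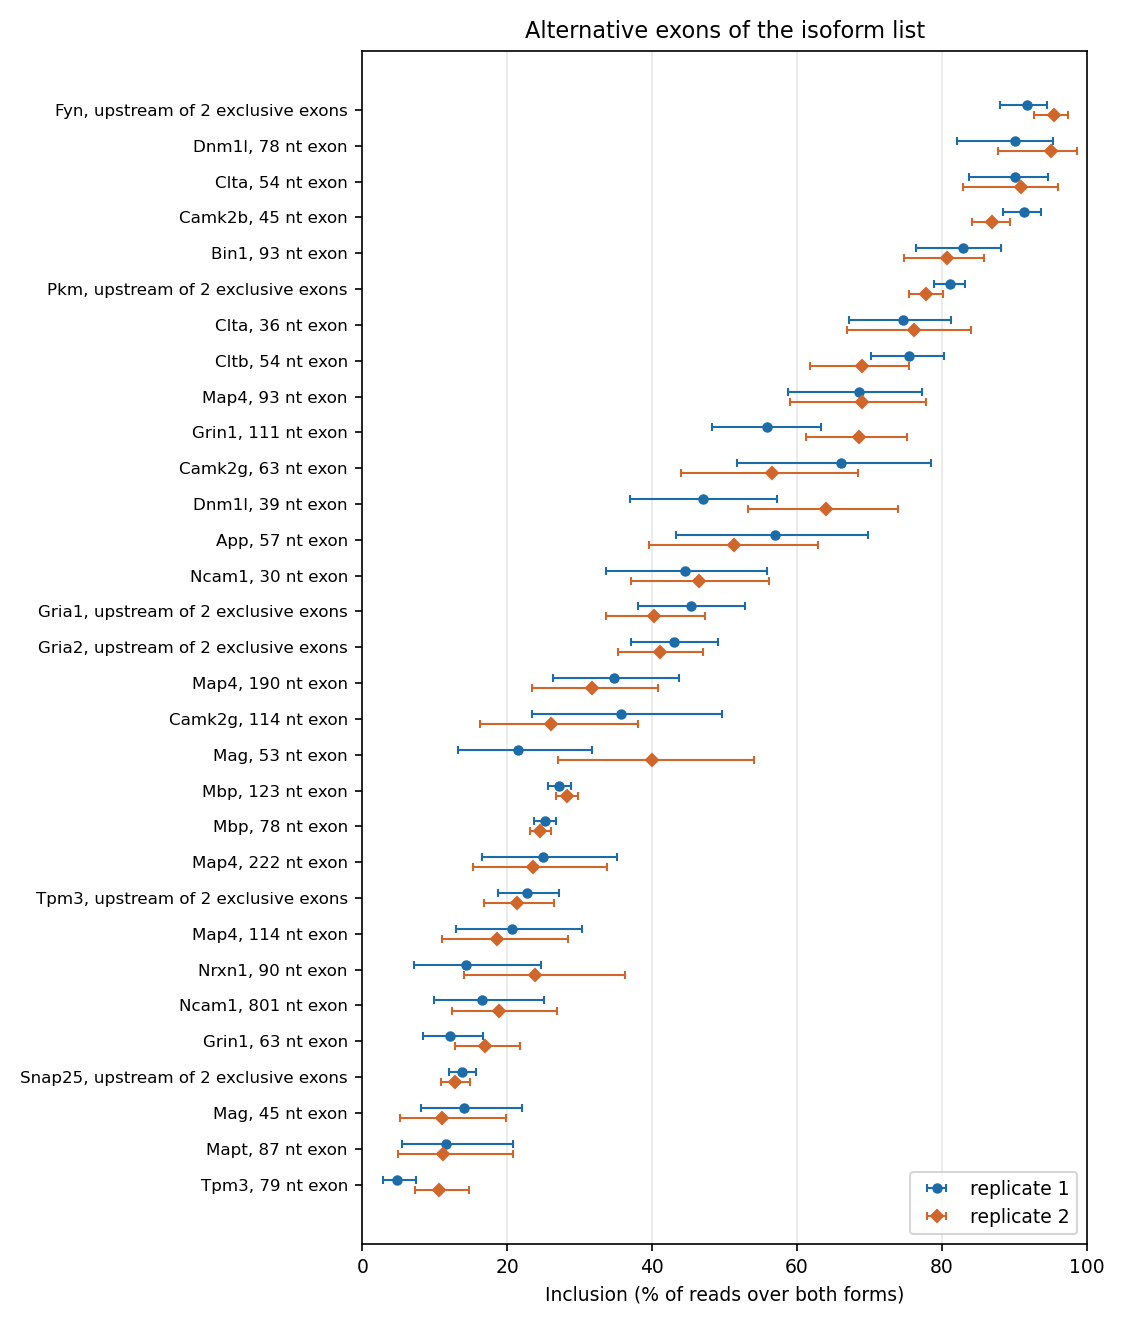
Inclusion of alternative exons of the isoform list (percent of reads over both forms, x axis) in replicate 1 (circles) and replicate 2 (diamonds), for events with at least 50 reads in each library and mean inclusion between 5% and 95%, a few genes left out. Bars are exact 95% binomial intervals. The intervals of the 2 libraries overlap for most exons, as for the 78-nt exon of Mbp at 25.2% and 24.5%.

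Inclusion of microexons differed widely between genes, and those of at most 14 nt were almost never read as included. That held also where no skipping form is annotated: 0 of 9 such exons had an inclusion read, with 3221 reads passing over them, while a 12-nt exon of the dynamin gene Dnm2, named after values were seen, was included in 35.9% and 42.9% of reads. The median inclusion read for all 135 annotated cassette exons of at most 27 nt, these included, was 14.5% (quartiles 0 to 86.2), against 85.2% (1.61 to 99.8) for 4315 longer ones. This difference of -70.8 percentage points (two-sided permutation test with 100000 resamples, p = 0.00025) was -17.6 points between means (39.4% and 57.0%; p = 1e-05, the smallest possible). For the 114 exons of 15 to 27 nt alone, a limit set after seeing the data, the median was 54.1% and the difference from exons over 27 nt was -31.1 points (permutation p = 0.07). Cassette exons of 28 to 51 nt had a lower median, 37.7%. The receptor phosphatase gene Ptpra included its 27-nt exon in 50.1% ± 1.55 of reads, the WAVE complex gene Nckap1 its 18-nt exon in 54.0% ± 3.11, the plastin gene Pls3 a 27-nt exon in 83.1% ± 3.81 and the endocytic gene Snap91 a 15-nt exon in 97.6% ± 0.0160 (SD, n = 2). The 27-nt exons of Kif5c and Nnat (0 and 0.325% ± 0.459) and the 21-nt exon of Tmed2 (0) were nearly or fully skipped. The 6-nt exons of Nsmf and Snap91 and the 12-nt exon of Vps29 had no inclusion read, and binomial limits are not given for them because of the 9 exons above.

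**Figure D5:**
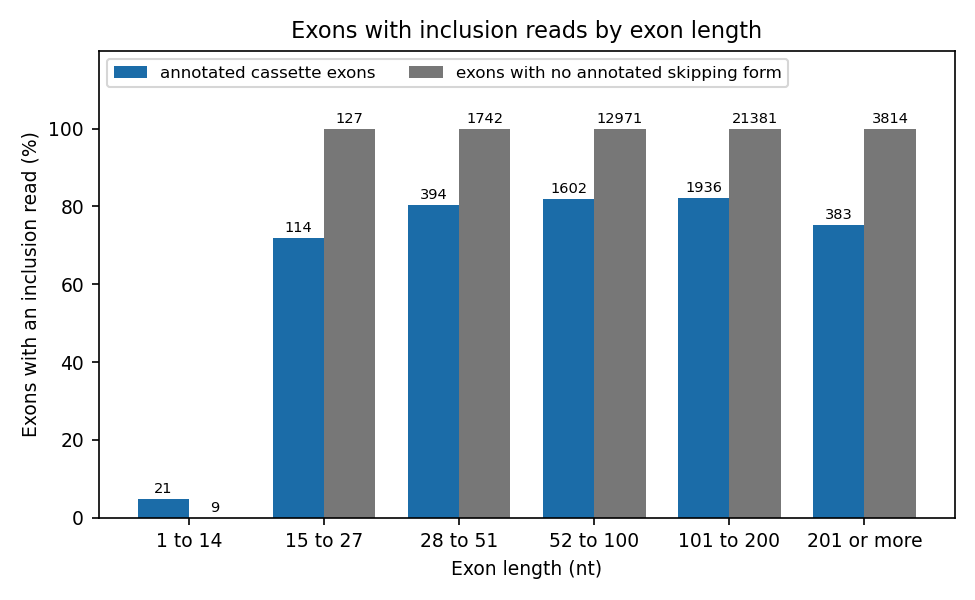
Share of annotated exons with at least 1 inclusion read (percent, y axis) by exon length in nt (x axis), for cassette exons and for exons with no annotated skipping form, with the number of exons above each bar. At most 14 nt it was 4.76% of 21 cassette exons and 0 of 9 others, and at 15 to 27 nt 71.9% of 114 and 100% of 127.

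Cassette exons had a length divisible by 3, which keeps the reading frame within coding sequence, more often than exons that were never skipped. The position of coding sequence was not used, so exons outside it are counted too. Of the 1232 cassette exons with mean inclusion between 5% and 95%, 740 or 60.1% (95% interval 57.3 to 62.8) had a length divisible by 3. Of 32457 internal exons with at least 20 reads in each library and no skipping read, 12573 or 38.7% (38.2 to 39.3) did (two-sided Fisher's exact test, p = 1.7e-49). Those divisible by 3 include the 78-nt and 123-nt exons of Mbp and the 63-nt and 111-nt exons of Grin1. The 190-nt exon of the microtubule gene Map4, in 33.2% ± 2.13 of reads (SD, n = 2), is not divisible by 3.

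Use of the leading transcript differed between the libraries in 159 of 6607 genes (two-sided Fisher's exact test, adjusted p at most 0.05), and it did so mostly through 1-exon models. The leading model had 1 exon in 90 of the 159, where unannotated 1-exon models of a gene in 1 class count as 1 model. The 5 genes with the largest difference in share were Lor (0 and 98.1% of reads), Kctd4 (97.7% and 0), Slc12a5 (97.7% and 0), Adar (91.0% and 0) and Traf3 (90.6% and 0). In each the leading 1-exon models were called genomic in 1 library and incomplete splice matches in the other. With the 1-exon models of a gene pooled across classes, an alternative added after seeing the data, 70 genes differed, and with annotated transcripts only, 5 did. In these 5 the share of the leading transcript was 68.6% and 84.4% in Ddx5, an RNA helicase gene, 83.7% and 70.9% in Rtn1, a reticulon gene, and 34.1% and 25.6% in Gpm6b, a membrane glycoprotein gene. It was 73.8% and 34.6% in Usp15 and 91.6% and 68.2% in Enpp2, and the adjusted p ran from 9.78e-12 to 0.0286 by the same exact test. In the isoform list 7 of the 50 genes passed with all models. Those with a spliced leading transcript were Mbp, a transcript of 5 exons (39.7% and 45.0%), and Tpm1, a transcript of 8 exons (39.7% and 60.5%; adjusted p = 0.0473). Neither passed with annotated transcripts only.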

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

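Reads on loci antisense to annotated genes made up 9.22% of replicate 1 and 7.15% of replicate 2, and reads on intergenic loci 1.35% and 1.01%. These are a signal in models that no comparison of the report used, above the limit that a count of 0 allows. The tests in this part, apart from those on the second choroid plexus list and on A-rich sequence, were chosen after the result was seen.

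The antisense reads were almost all on 1-exon models (97.6% and 97.2% of them), in 22335 and 16319 loci. The largest with no annotated gene on the same strand lay opposite Slc1a2, an astrocyte glutamate transporter gene, with 2581 and 3254 CPM against 194 and 339.8 CPM for the gene itself. Opposite Shank1 of the postsynaptic density list stood 1654 and 1452 CPM, against 47.9 and 39.4 CPM for the gene. Opposite Cplx2 of the vesicle release list stood 2147 and 1389 CPM. List levels leave these antisense reads out. Reads given the wrong strand at 1 rate for all genes would follow the sense reads. Yet at least 51.4% of antisense reads in each library lay at genes with more antisense than sense reads. Spike-ins had 0.776% and 0.907% antisense reads, so a wrong-strand rate shared by all genes was not borne out. Wrong strands at certain loci only could not be tested, since 1-exon models hold no splice site that shows the strand. Priming on A-rich sequence might give such models: of 895 models with 1 exon and at least 20 reads, 454 had sequence at hand, and 47.4% of these had at least 60% A in the 20 nt past the end, against 2.71% of random positions, which is between the 2 predicted outcomes. No biological explanation was tested.

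Choroid plexus markers in replicate 1, with Ttr at 4558 and 5.63 CPM, could come from choroid plexus tissue in that pool. In a second list, 75% of the 4 genes with at least 10 reads were higher in replicate 1, under the 80% set beforehand. The test therefore did not decide it, and with 4 genes the 80% could be met only if all 4 were higher. Higher were Otx2, Calml4 with 24.8 and 2.25 CPM and Sostdc1 with 44.5 and 2.25 CPM, but not Car12 with 24.8 and 29.3 CPM. The whole list had 134 and 34 reads, of which Car12 held 29 and 26. Reads under another name in replicate 2 were ruled out as the cause, since any name over Ttr reached 0.123% of the replicate 1 level. Apart from such tissue in the pool, no biological explanation was tested, since both libraries belong to 1 group.

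Exons of at most 14 nt had almost no inclusion reads, which may come from alignment. Of 9 such exons with no annotated skipping form 0% had an inclusion read, with 3221 reads passing over them, while all 127 of 15 to 27 nt had them, which is consistent with short exons being missed in alignment. Skipping of the shortest cassette exons in this tissue could not be told apart from it, as 4.76% of 21 cassette exons had inclusion reads (1 exon, in Dnm2). No biological explanation was tested further.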

How the results depend on the processing

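Of 49 recomputed values for 9 results, 36 kept the side of the threshold (results with a test), a similar count, or a value within 1 SD of the libraries, 12 moved, 1 became weaker and 0 reversed; the cause was not tested unless stated. For the annotated share with either library left out this holds by construction, since each of 2 libraries lies within 1 SD of their mean. The 36 did not all keep their size: the microexon difference was -17.6 points between means, and 10898 genes had at least 5 reads in each library. Without genomic models the annotated share was 70.2%, since fewer reads are counted. The 1266 differing genes became 289 with at least a 2-fold difference, a stricter limit, and 393 with the trend with transcript length removed. The 159 genes with differing leading transcripts became 14 without incomplete, genomic and antisense models, 5 with annotated transcripts only and 70 with 1-exon models pooled across classes. The multi-isoform share was 43.1% with a limit of 5%, 13.7% with 20%, 33.7% with incomplete matches kept and 22.8% with annotated transcripts only, and 35.5% to 36.3% with either library left out, where 1 library has to pass. The microexon difference was -31.1 points for 15 to 27 nt (permutation p = 0.07). The length trend, 15 to 27 nt, pooled models, merged genes and TMM list levels were chosen after seeing the data. With either library left out the annotated share was 64.6% to 66.0%, the microexon difference -72.8 points and the frame difference 19.0 to 20.97 points. Of 58 single list levels recomputed with both libraries kept, 24 stayed within 1 SD of the libraries; with a library left out that holds by construction. In those 58, annotated transcripts only gave 0.2 to 0.980 times the level and TMM-scaled totals 1.13 to 1.19 times. The latter range includes the change from all reads to the fewer reads of annotated genes. Depth limited genes with 0 reads to 2.57 and 3.38 CPM.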

Other observations

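Outside the isoform list, Mapk9 and Mapk14 used both members of an exclusive exon pair at nearly equal rates. The upstream 72-nt exon of Mapk9, a Jun kinase gene, was in 50.5% ± 0.0289 of reads and the upstream 80-nt exon of Mapk14, a p38 kinase gene, in 49.8% ± 5.16 (SD, n = 2). The upstream exon was in 23.4% ± 0.684 of reads of the flotillin gene Flot2, 28.9% ± 4.44 of the acyl-CoA synthetase gene Acsl6, 63.6% ± 8.73 of the histone gene H2afy and 38.96% ± 3.39 of the phosphatase gene Acp1. In all 164 pairs of exons had enough reads holding 1 member without the other, and 51 had a mean between 5% and 95%. Reads that hold both members were not counted, so not all of these pairs are strictly exclusive. The 51 include the 54-nt and 36-nt exons of Clta, which 118 and 80 reads held together. These genes were chosen after values were seen.

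The 93-nt repeat exon of Mapt, the tau gene (chromosome 11, 104318157 to 104318249), was in 80.95% of reads in replicate 1 and 73.6% in replicate 2, where the skipping form is unannotated. Some unannotated transcripts matched an annotated one with an exon of at most 14 nt left out, with 369 and 341 reads in Sept7, 228 and 143 in Mpc1, and 164 and 110 in Phb2. Such short-exon matches took 1.07% and 0.957% of unannotated spliced reads, and matches after closing annotated gaps of at most 5 nt, as in Oaz1 and Oaz2, 1.81% and 1.31%.

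The inclusion form of the 75-nt exon of Enpp2 stood at 35.1 and 47.3 CPM in the 2 libraries and the skipping form at 477 and 115.9 CPM. The 3 intergenic loci with the most reads lay at chromosome 15, 103619061 to 103619240 (291.9 and 212.7 CPM), chromosome 4, 133096112 to 133101553 (166 and 291 CPM), and chromosome 1, 171300693 to 171300876 (253 and 126 CPM).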
